A study of Mus musculus with 16 samples.

How the data were processed

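Total RNA from mouse liver was depleted of ribosomal RNA and made into directional sequencing libraries, per the labels' protocols. The submitters' processing notes name the genome build mm10. The aligner and the counting method are not given in the sources used here. The sample descriptions refer to total counts that were quantile-normalized in separate workbooks for NCD with HFD and for misty with db. Those workbooks were not used here.

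The table used here, as deposited, holds gene annotation: chromosome, position and strand, Ensembl identifier, symbol and biotype of each gene. Of its 11 columns, 2 hold only numbers, and both are annotation version numbers. The tests of expression and the list tests fixed before the data were examined were therefore not run here, and no test was made.

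Gene positions were read from the table with Python 3.11.15 and are 1-based. Of the table's identifiers, 49326 were in GENCODE M21, and 45125 of these, or 91.5%, had the same chromosome, start, end and strand there. Symbols of the gene lists were matched exactly. Synonyms came from a RefSeq gene table of GRCm38. Genes were counted as overlapping where their spans shared at least 1 base. Lepr is described because the rule fixed in advance names it regardless of expression. Some items that the rule names are not reported here. The 3 genes given as examples of overlap, Pparg, Ppargc1a and Srebf1, and the unmatched symbols were chosen after their annotation was seen. The sex chromosome genes, which that rule names as a check, are counted among the listed symbols but not described singly. That check concerned expression and was not made.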

Results

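Liver RNA from 4 groups of mice was sequenced, with 4 libraries per group and 16 in all. C57BL/6 wild-type mice aged 24 weeks formed the groups labelled NCD and HFD, abbreviations that the labels do not expand. Mice aged 10 weeks formed the db/db group and its misty/misty lean control group. These groups differed from NCD and HFD in both age and strain. Between the models, age, strain and model therefore cannot be told apart. The db/db genotype carries a homozygous mutation of the leptin receptor gene Lepr. The design implies a comparison of HFD with NCD, a comparison of db/db with misty/misty, and a search for genes that changed in both models. Expression values of these libraries were not analysed here, so none of these comparisons was made and no expression level, fold change or depth is reported. The values below are gene positions and counts of annotated genes, which have no replicates and no measurement error.

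The annotation table of the series listed 49585 genes in 11 columns, and 0 of these columns were named for a library or group. Protein-coding genes made up 21973 of the entries, or 44.3%. Processed pseudogenes numbered 7289 and long intergenic noncoding RNAs 4255. A symbol was shared by more than 1 gene in 93 cases, covering 186 genes.

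Lepr, the gene mutated in db/db mice, occupied chromosome 4 from 101717404 to 101815352 on the plus strand and was annotated as protein-coding. Its position was identical in the table and in GENCODE M21, which is built on GRCm38 (mm10).

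A set of 38 lists of liver pathway genes and cell type markers, fixed before the data were examined, held 575 different symbols. The table listed 569 of them under the same symbol, and every symbol was found for 33 lists. Of the 6 symbols that were not matched, Atp5f1a, Atp5f1b, Bmal1, Sepp1 and Trarg1 appeared under another name of the same gene, as Atp5a1, Atp5b, Arntl, Selenop and Tusc5. The first 4 of these names were themselves in the lists, so only Tusc5 was a gene not already matched. The remaining symbol, G6pc1, had no RefSeq synonym among the annotated symbols. Its absence by name therefore does not show that the gene is missing from the annotation. G6pc, given beside it in the gluconeogenesis list, was matched. Of the 569 matched symbols, 219 named a gene that overlapped another annotated gene by at least 1 base. An overlap with a gene on the opposite strand was found for 167, among them Pparg, Ppargc1a and Srebf1, and for 73 when only protein-coding partners were counted. An overlap on the same strand was found for 86, including Ppargc1a and Srebf1, and for 21 when only protein-coding partners were counted. These overlaps are of whole gene spans, introns included. No such count was made over all 49585 genes, so these counts do not tell whether listed genes overlap others more often.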

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

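The alternatives below were chosen after the annotation was seen, and the alternatives fixed in advance, all of which concern expression values, were not run. Accepting RefSeq synonyms raised the matched symbols from 569 to 574 of 575. However, 4 of the 5 added symbols name a gene already listed under its other symbol, so 1 gene was added. The symbol still unmatched was G6pc1, which had no such synonym. These are counts of symbols, so they do not show that a listed gene is missing from the annotation. Counting only protein-coding partners lowered the listed genes with an overlap on the opposite strand from 167 to 73 and those with an overlap on the same strand from 86 to 21, because fewer partners were then eligible. No paired analysis was possible because no expression values of the libraries were used here.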
